A study of Mus musculus with 30 samples.

How the data were processed

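RNA was sequenced from 12 NSPC libraries, 6 forebrain explant libraries and 1 forebrain library, and ChIP libraries were made with pan-Kcr and pan-Kac antibodies from NSPCs and with H3K9cr and H3K9ac antibodies from the forebrain. The authors processed RNA reads with Salmon 1.0.0 and DESeq2 1.26.0 and ChIP reads with Bowtie2 2.3.5.1 and MACS2 2.2.5 on GRCm38, per the labels. The TPM values of the NSPC and forebrain RNA were made by the authors and deposited as 1 table of 53974 genes. Each column sums to between 998182 and 999495, so a small part of each library is not in the table, and no read counts are given. For the explants the authors deposited 1 table that compares crotonate with control. Its signal column is the mean of DESeq2-normalized counts over libraries, per the file headers. The log2 fold changes and their SE in it were fitted by the authors with DESeq2. Its score column is the fold change divided by its SE, as deposited by the authors. The p value and adjusted p columns were also made by the authors, who wrote an adjusted p of 1 where none was computed. The direction, crotonate against control, is given only by the name under which the table was deposited. The forebrain peak lists hold, as deposited by the authors, a score, the fold enrichment at the summit as a ratio to the control, and the -log10 p and -log10 q of MACS2. The 6 NSPC peak lists hold positions alone, as deposited, so their calling threshold is not known.

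Each sample was placed in its group from its title, and each peak list was assigned to the library whose mark, treatment and tissue its name gives. The comparisons, tests, gene lists, thresholds and most alternatives were fixed before the data were examined. TPM values were taken as log2(TPM + 1). Genes with at least 1 TPM in at least 4 of the 12 NSPC libraries were tested with limma 3.58.1 (R 4.3.3) in 1 fit of 3 groups, with eBayes and a trend. The 3 pairwise contrasts were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fixed gene lists with at least 5 tested members were tested with limma's camera at a correlation of 0.01 between genes and adjusted over the lists of a contrast. On simulated NSPC data without true differences but for chosen genes, limma recovered 60% of genes changed 1.25-fold, 74% of those changed 2-fold and 94% of those changed 4-fold, and called 14 of 13392 unchanged genes. Camera called 5 of 5 shifted lists and 0 of 15 others. These lists held random genes with independent noise, so false calls from correlation between genes were not measured.

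The replicate numbers were checked for pairing. After removal of group means the 12 correlations between libraries with the same number ran from 0.119 to 0.241, and the 36 between libraries with other numbers from -0.197 to 0.0993. Xist and Y-linked genes also split the replicates the same way in all 3 groups, so the numbers pair the samples. The fit without this term was kept, as fixed, and a fit with the replicate number as a block was run as an alternative.

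For the explants the authors' adjusted p was used at 0.05 over the 14507 genes for which they computed one. The median of each list was placed among 10000 random lists of the same size drawn within 20 bins of mean expression, in place of camera, which needs values per library. Of 100 simulated lists without a shift 1 lay outside the central 95%, and of 100 shifted by 0.2 on the log2 scale 97 did. These genes were simulated independently of each other as well. No paired analysis was possible because the table holds no values per library. Overlaps of peaks of at least 1 bp were counted with bedtools 2.31.1, which found 700 of 700 overlaps among simulated peaks. The annotation used gives no strand, so a peak was assigned to a gene when it lay within 1 kb of either end of the gene, and not of its start alone. Positions were found for 13773 of the tested genes (92.7%). Genes were classed by peaks in both lists, gained, lost or in neither. The median log2 fold change of each class was compared with that of genes with a peak in both, by 100000 two-sided permutations within 10 bins of control expression, and intervals come from 2000 bootstrap resamples of genes. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables and figures.

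Named genes follow a fixed rule. For each treatment against control these are the 10 genes per direction with the largest log2 fold change past the threshold whose treated libraries all lie beyond all controls, with a mean of at least 5 TPM (explants, 50 normalized counts) in the higher group and without predicted genes. For MS-275 against crotonate 5 per direction were taken. In the explants the condition on libraries could not be applied, since the table holds no values per library. From each list with a call, or with at least 3 changed members, the rule takes the 2 members with the smallest adjusted p in the list's main direction, the first in the other direction and the most expressed member that did not pass. Class I deacetylases and the acyltransferases Ep300 and Crebbp are always included, and for peaks the 3 widest gained. Some genes that the rule takes are not given in the text. To keep it short, members that did not pass are mostly left out, and lists without a call are given as counts of members. Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum of 5 TPM, median-of-ratios scaling, quantile normalization, a replicate block, a fit of the 8 compared libraries, eBayes without trend, a threshold of 1 on the log2 fold change and each replicate left out in turn. For lists they were a correlation estimated per list and fry. For peaks they were a 50% overlap, merging within 1 kb, a -log10 q of at least 5 and windows of 3 kb. The bisulfite, IgG and input libraries were not analysed here.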

Results

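The series holds 30 mouse samples in 17 groups, all from the embryonic forebrain at E13.5 or from neural stem and progenitor cells (NSPCs) cultured from it. RNA was sequenced from NSPCs of the C57BL/6 strain after 24 h with the solvent DMSO (control), with 10 mM crotonate, a short-chain fatty acid, or with 1 µM MS-275, an inhibitor of class I histone deacetylases, in 4 biological replicates each. RNA from forebrain explants of the ICR strain was sequenced in 3 control and 3 crotonate libraries. Chromatin immunoprecipitation (ChIP) with antibodies against crotonylated lysine (Kcr) and acetylated lysine (Kac) was sequenced from NSPCs in 1 library per antibody and treatment. The untreated forebrain had 1 library each for H3K9cr and H3K9ac, histone H3 crotonylated or acetylated at lysine 9, and 1 for RNA. The RNA tables give no read counts per library, and the peak lists give no read numbers, so the depth of each library is unknown. In the NSPC libraries 13444 to 13696 genes reached 1 TPM, an abundance scaled for length and depth, in the controls, 14388 to 14595 with crotonate and 14565 to 14854 with MS-275. Between libraries of a group the correlation of log2 values across genes was at least 0.981. Positions below are on GRCm38 and counted from 1.

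The comparison of crotonate with control asked which genes change in NSPCs given crotonate. H2-Ab1, a chain of the MHC class II molecule (chromosome 17, 34263227 to 34269418), rose from 1.34 ± 0.640 to 27.0 ± 1.98 TPM (SD, n = 4 each), with a log2 fold change of 3.61 (SE 0.14). Tpm2, a tropomyosin (chromosome 4, 43513726 to 43523583), rose from 2.59 ± 0.697 to 31.2 ± 0.769 TPM, and Gpc3, a cell-surface heparan sulfate proteoglycan (chromosome X, 52272426 to 52613974), from 0.859 ± 0.368 to 16.4 ± 1.16 TPM. Rian, an imprinted noncoding RNA, rose 9.66-fold, Kcnt1, a potassium channel, 11.4-fold, and Rtn4rl2, a receptor of the Nogo receptor family, 11.3-fold. Lbhd2 and Mgarp, a mitochondrial protein, rose 12.9-fold and 12.2-fold. Snurf, which shares its transcript with Snrpn, had a log2 fold change of 3.36 with an SE of 0.99, so the value is uncertain. Among the genes that the naming rule takes, Tfrc, the transferrin receptor that brings iron into cells (chromosome 16, 32608896 to 32632794), fell from 86.3 ± 17.1 to 31.2 ± 3.98 TPM, a log2 fold change of -1.42 (SE 0.13). Apln, which encodes a peptide hormone (chromosome X, 48025146 to 48034853), fell from 103 ± 10.7 to 50.9 ± 3.39 TPM, and Aven, an inhibitor of cell death, from 14.9 ± 2.46 TPM to 0.424 of that level. Ndc80, a kinetochore protein, Kif20a, a mitotic kinesin, Cep89, a centrosomal protein, Fam72a and Aldoc, a glycolytic aldolase, fell to between 0.509 and 0.548 of the control level. Rsc1a1 and AA465934, both at or below 6.82 TPM, fell with adjusted p of 0.0411 and 0.0172. The call of Rsc1a1 ended with a pseudocount of 0.1, without a filter and without trend (adjusted p 8.6e-04 to 0.269 over the alternatives) and in 7 of 8 fits with a library left out. That of AA465934 ended without control 2 or crotonate 3 (0.0104 to 0.0532 over libraries left out).

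**Figure D1:**
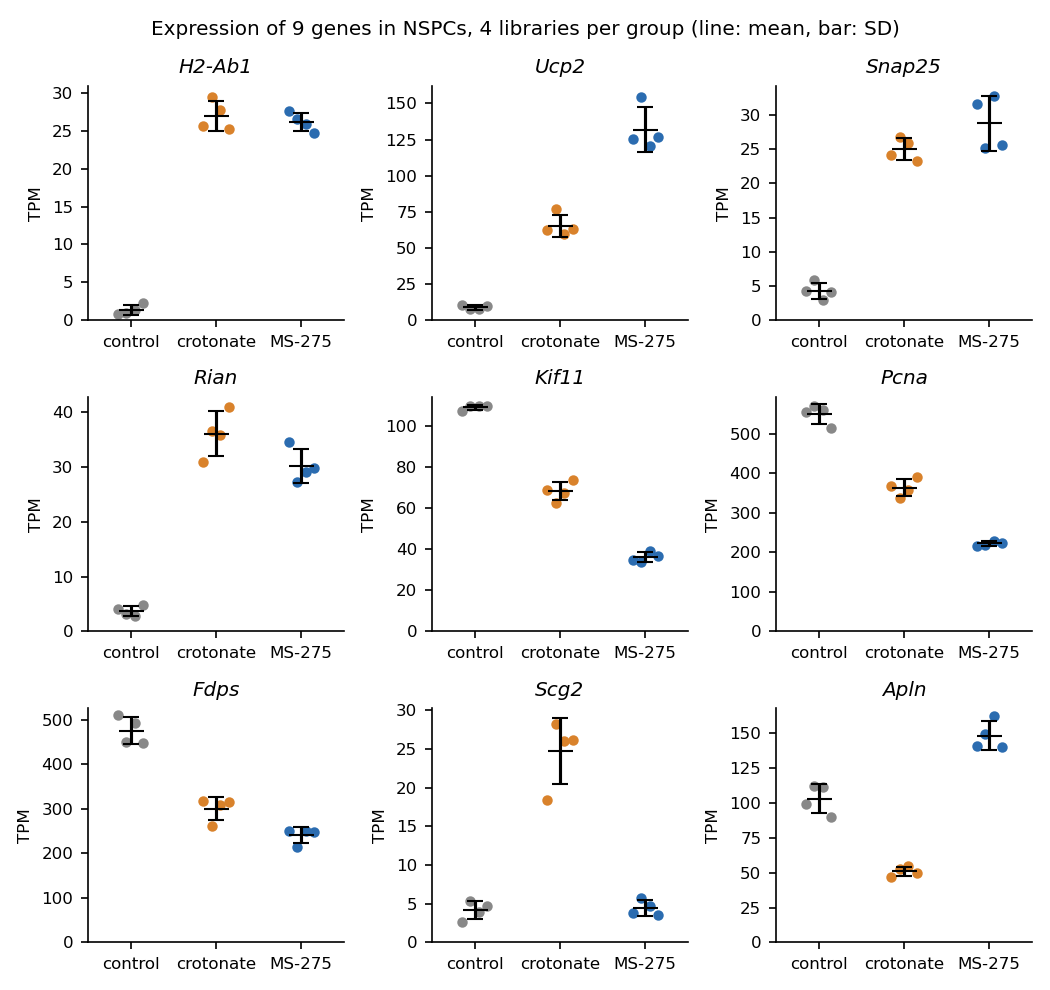
TPM of 9 named genes in the 4 control, 4 crotonate and 4 MS-275 NSPC libraries (points), with the mean (line) and SD (bar) of each group. Apln lay at a mean of 103 TPM in control, 50.9 TPM with crotonate and 148 TPM with MS-275, and Scg2 at 4.16, 24.7 and 4.42 TPM.

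Groups of neuronal genes rose with crotonate. Of 29 tested genes of synapse and excitability, 24 rose and none fell, with a median log2 fold change of 0.69 beside 0.09 for all genes. Snap25, a component of the vesicle fusion machinery, rose from 4.32 ± 1.18 to 25.0 ± 1.62 TPM, and Syn1, a synaptic vesicle protein, from 17.2 ± 1.42 to 37.3 ± 2.24 TPM. The list passed limma's camera test at an adjusted p of 4.3e-06, and had an adjusted p of 0.0539 with an estimated correlation. Among 19 neuroendocrine genes repressed by REST, a silencer of neuronal genes, 15 rose and none fell. Vgf, a neuropeptide precursor, rose 6.09-fold and Scg2, a secretory granule protein, 5.93-fold, with a camera adjusted p of 3.1e-04 and an adjusted p of 0.332 with an estimated correlation. Of 27 genes of neuronal differentiation 19 rose and 2 fell. Celf4, an RNA-binding protein of neurons, rose 5.64-fold and Ina, a neuronal intermediate filament, 2.09-fold, while Map2, a microtubule-associated protein of dendrites, fell from 303 ± 8.83 to 244 ± 11.1 TPM. That list had an adjusted p of 0.00462, and an adjusted p of 0.332 with an estimated correlation.

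Interferon response genes and imprinted genes rose as well. Of 17 tested interferon genes 14 rose and none fell, with a median log2 fold change of 0.77, including B2m, the light chain of MHC class I, up 2.34-fold, and the class I heavy chain gene H2-D1, from 21.2 ± 1.38 to 51.7 ± 3.93 TPM. The adjusted p was 1.2e-04, and 0.0475 as the adjusted p with an estimated correlation, but 0.187 with an estimated correlation and a replicate block, where the call ended. Of 20 imprinted genes 15 rose and none fell, with the neighbouring noncoding RNAs Rian and Meg3 up 9.66-fold and 9.67-fold, an adjusted p of 2.9e-04 and an adjusted p of 0.0539 with an estimated correlation. Among 22 genes of fatty acid oxidation and PPAR targets 16 rose and 3 fell. Ucp2, a mitochondrial carrier, rose from 9.04 ± 1.63 to 65.5 ± 7.67 TPM and Slc25a20, the carnitine carrier, 1.58-fold, while Hadhb, a subunit of the trifunctional protein, fell to 0.824 of control. The adjusted p was 0.0278, 0.378 as the adjusted p with an estimated correlation, and 0.0769 after median-of-ratios scaling.

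Cell cycle genes fell with crotonate. Of 30 genes of G2/M and mitosis 29 fell and none rose, with a median log2 fold change of -0.58. Kif11, a spindle motor, went from 109 ± 1.17 to 68.2 ± 4.44 TPM, and Birc5, a subunit of the chromosomal passenger complex, from 165 ± 3.72 TPM to 0.599 of that level. The adjusted p was 1.4e-20, and 0.210 as the adjusted p with an estimated correlation. Of 28 genes of G1/S and DNA replication 26 fell and none rose, with a median of -0.47. Pcna, the sliding clamp of DNA polymerase, fell from 550 ± 24.6 to 364 ± 22.0 TPM and Mcm7, a subunit of the replicative helicase, from 202 ± 4.53 to 147 ± 7.31 TPM, at an adjusted p of 2.3e-15 and an adjusted p of 0.0539 with an estimated correlation. The most highly expressed member, cyclin D1 (Ccnd1), did not pass, at 1375 ± 40.1 TPM in control and 1374 ± 82.8 TPM with crotonate.

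Metabolic and stress groups fell in part. Of 23 cholesterol biosynthesis genes 19 fell and none rose, with a median of -0.45, among them Fdps, which makes farnesyl diphosphate, to 0.632 of control, and Sqle, squalene epoxidase, to 0.666 of control. The adjusted p was 5.5e-11, and 0.350 as the adjusted p with an estimated correlation. Of 14 fatty acid synthesis genes 8 fell and 3 rose. Acly, which makes cytosolic acetyl-CoA, and the elongase Elovl6 fell to 0.730 and 0.742 of control, while malic enzyme Me1 rose 1.40-fold. That list had an adjusted p of 0.00811, an adjusted p of 0.557 with an estimated correlation, and 0.139 after quantile normalization. Of 21 genes of the integrated stress response 11 fell and 4 rose. The transcription factor Atf4 and the amino acid transporter Slc7a5 fell to 0.629 and 0.621 of control, and Pycr1, an enzyme of proline synthesis, rose 1.83-fold, at an adjusted p of 4.1e-04 and an adjusted p of 0.359 with an estimated correlation. Of 14 acyl-lysine readers 4 fell and none rose, with log2 fold changes of -0.30 and -0.41 for the bromodomain proteins Brd2 and Brd3, an adjusted p of 0.00195 and an adjusted p of 0.332 with an estimated correlation. Of 11 heat shock genes 7 fell and 2 rose. Hsp90aa1, a chaperone of the HSP90 family, and Dnaja1, a cochaperone, fell to 0.755 and 0.799 of control, while the small heat shock gene Hspb1 rose from 0.601 ± 0.267 to 7.48 ± 1.91 TPM. The heat shock list's median was -0.17 and its mean 0.22, and camera gave a downward call at an adjusted p of 0.0467, with an adjusted p of 0.535 with an estimated correlation, 0.109 after median-of-ratios scaling, 0.294 after quantile normalization and 0.0674 with a replicate block.

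Of the class I deacetylases Hdac1 rose from 113 ± 4.23 to 143 ± 4.62 TPM (log2 fold change 0.34, adjusted p 2.1e-05) and Hdac2 from 233 ± 7.48 to 258 ± 15.5 TPM (0.14, adjusted p 0.0156). After median-of-ratios scaling the change of Hdac2 was 0.01 and its call ended (adjusted p 0.00249 to 0.864 over the alternatives). Hdac3, Hdac8 and the acyltransferases Ep300 and Crebbp did not pass, with log2 fold changes of -0.06, 0.28, 0.11 and 0.06, and the signs of Ep300 and Crebbp turned with scaling. The 25 genes of neural stem cells and radial glia had 3 higher and 4 lower members and no call, at an adjusted p of 0.289. Among the 27 lists without a call were also those of astrocytes, oligodendrocytes, endothelium and Cajal-Retzius cells, with 6, 7, 3 and 2 members higher and 3, 0, 0 and 1 lower. Hox, microglia, erythroid and choroid plexus lists had fewer than 5 tested members each. Adjusted over the list alone, the counts for called lists were unchanged except for synapse (25 higher), interferon (15 higher), G1/S (1 higher and 26 lower), readers (3 lower), the integrated stress response (4 higher and 12 lower) and heat shock (4 higher and 7 lower).

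Over 14857 genes tested with limma, 7152 passed an adjusted p of 0.05 between crotonate and control, 4796 higher and 2356 lower, and 914 and 17 of them changed at least 2-fold. Median-of-ratios scaling moved the median of all genes by -0.12 on the log2 scale and gave 3503 higher and 4213 lower genes. Camera called 13 of 40 lists, 6 upward and 7 downward, and 1 of them (interferon) with an estimated correlation. For 51 of the 52 named genes that passed, all 4 crotonate libraries lay beyond all 4 controls, and Hdac2 had 3 of 4. The naming rule requires this of the leading genes and takes list members by their adjusted p, so the count describes the selection. The control received DMSO and no vehicle is stated for crotonate. An effect of the solvent can thus not be told apart from that of crotonate, here or in the comparison with MS-275. The control shares the solvent of the MS-275 group only as far as the labels say.

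**Figure D2:**
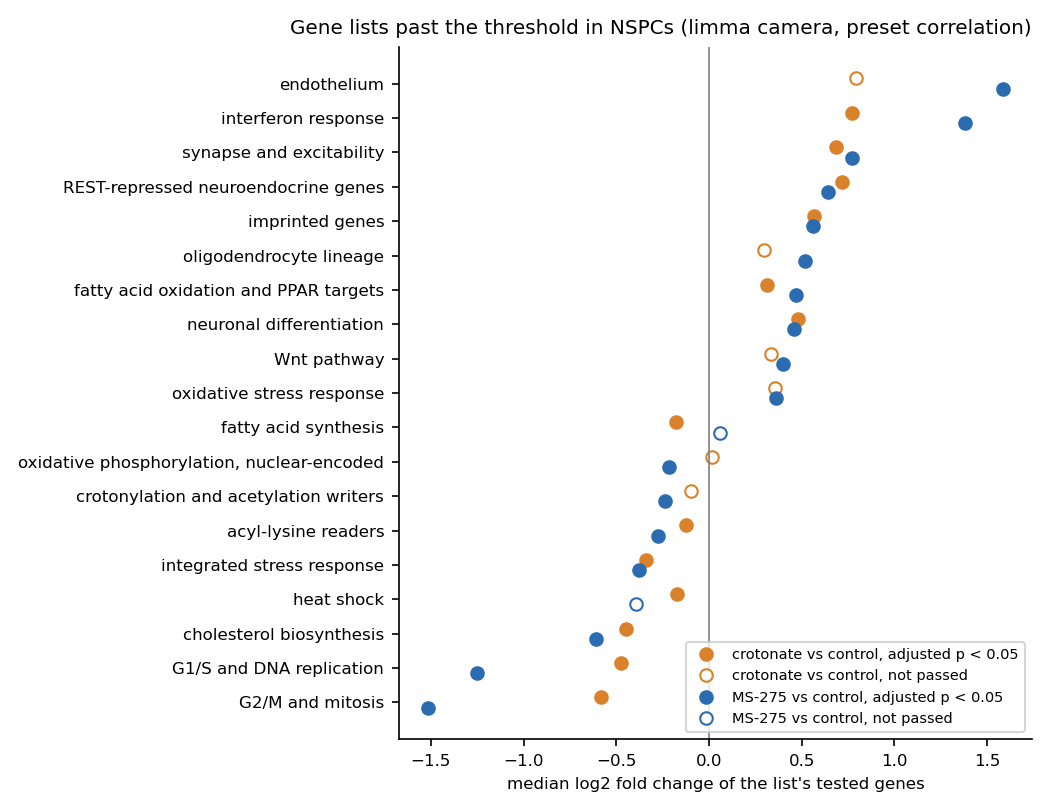
Median log2 fold change of the tested members of each gene list past the camera threshold in either treatment, crotonate (orange) and MS-275 (blue) against control, with filled points for an adjusted p under 0.05. The lowest points are those of G2/M and mitosis, at -0.58 with crotonate and -1.52 with MS-275.

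MS-275 was compared with control to find the response to inhibition of the deacetylases themselves. Mgarp rose 30.8-fold to 41.0 ± 4.54 TPM (SD, n = 4 each), a log2 fold change of 4.24 (SE 0.20), and Ucp2, the mitochondrial carrier (chromosome 7, 100493337 to 100499629), from 9.04 ± 1.63 to 132 ± 15.4 TPM, a log2 fold change of 3.73 (SE 0.12). H2-Ab1 and Tpm2 rose 19.4-fold and 14.4-fold. Mdfi, an inhibitor of myogenic transcription factors, rose 21.5-fold, Got1l1, related to an aspartate aminotransferase, 19.1-fold, and the protease gene Capn5 16.1-fold, while the T-type calcium channel gene Cacna1g and Syt3, a synaptotagmin, had log2 fold changes of 3.45 and 3.36. Cdc20, an activator of the anaphase-promoting complex (chromosome 4, 118432901 to 118437343), fell from 180 ± 6.27 to 41.4 ± 4.28 TPM, a log2 fold change of -2.10 (SE 0.07). Cenpa, the centromeric histone H3 variant (chromosome 5, 30666877 to 30674837), fell from 222 ± 29.6 to 51.5 ± 3.13 TPM. Spc24, a kinetochore protein, Pif1, a DNA helicase, Hirip3, Cdca2, the DNA glycosylase gene Neil3, the mitotic kinase gene Nek2 and Sapcd2 fell to between 0.231 and 0.262 of control. Hist1h2af, a histone gene without a position in the reference used, fell from 5.37 ± 3.36 to 0.188 ± 0.376 TPM.

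All tested members of both cell cycle lists and of the cholesterol list fell with MS-275. The 30 genes of G2/M and mitosis had a median log2 fold change of -1.52, with Kif11 at 36.2 ± 2.35 TPM beside 109 ± 1.17 TPM in control and the checkpoint kinase gene Bub1 at 0.334 of control. Camera gave an adjusted p of 2.0e-20, and 0.178 was the adjusted p with an estimated correlation. The 28 genes of G1/S and DNA replication had a median of -1.25, with Mcm7 and Mcm5 at 0.407 and 0.327 of control, an adjusted p of 2.1e-17 and an adjusted p of 0.0748 with an estimated correlation. The 23 cholesterol genes had a median of -0.61, with Mvd, an enzyme of the mevalonate pathway, at 0.447 of control. That list had an adjusted p of 1.2e-08, and an adjusted p of 0.332 with an estimated correlation.

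All 17 tested interferon genes rose, with a median of 1.38. The antiviral gene Rsad2 went from 0.466 ± 0.162 to 10.6 ± 1.27 TPM and H2-D1 rose 2.67-fold, at an adjusted p of 5.0e-06, an adjusted p of 0.017 with an estimated correlation, and 0.0818 with that and a replicate block. Of 22 genes of fatty acid oxidation and PPAR targets 19 rose and none fell, with Ucp2 up 14.6-fold and Slc25a20 up 2.03-fold, an adjusted p of 9.8e-05 and an adjusted p of 0.154 with an estimated correlation. Of 20 imprinted genes 17 rose and none fell, among them Rian, up 8.10-fold, and Grb10, an adaptor of growth factor receptors, up 2.84-fold, at an adjusted p of 7.8e-04 and an adjusted p of 0.0924 with an estimated correlation. Among 19 REST-repressed genes 17 rose and none fell. Vgf and Cdk5r2, an activator of the kinase CDK5, rose by 2.55 and 1.82 on the log2 scale, with an adjusted p of 3.7e-04 and an adjusted p of 0.220 with an estimated correlation. Of 27 neuronal differentiation genes 21 rose and 2 fell, with Celf4 and Elavl3, both RNA-binding proteins of neurons, up 5.78-fold and 1.80-fold and Elavl4 down to 0.522 of control. The adjusted p was 0.00156, and 0.191 as the adjusted p with an estimated correlation. Of 29 synapse genes 19 rose and 5 fell. Syn1 and Sv2a, both proteins of synaptic vesicles, rose 2.57-fold and 2.91-fold, and Cplx2, a complexin, fell from 32.3 ± 2.74 TPM to 0.309 of that level, at an adjusted p of 0.0151 and an adjusted p of 0.195 with an estimated correlation.

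Chromatin and respiratory genes fell together with MS-275. Of 11 writers of crotonylation and acetylation 7 fell and none rose, with the acetyltransferase genes Naa10 and Hat1 at 0.572 and 0.557 of control, an adjusted p of 0.00323 and an adjusted p of 0.15 with an estimated correlation. The acyltransferase genes Ep300 and Crebbp, also of this list, did not pass. Of 14 acyl-lysine readers 10 fell and none rose, with Brd2 and Brd3 at 0.691 and 0.636 of control, an adjusted p of 9.7e-04 and an adjusted p of 0.195 with an estimated correlation. Of 21 nuclear genes of oxidative phosphorylation 14 fell and 1 rose. Atp5a1, a subunit of ATP synthase, and cytochrome c (Cycs) fell to 0.796 and 0.683 of control, and Cox6a1 rose 1.09-fold. The call of Cox6a1 ended with a replicate block, without a filter, without trend and after median-of-ratios scaling, where its log2 fold change was 0.03 (adjusted p 0.00139 to 0.598 over the alternatives). The list's adjusted p was 9.7e-04, and 0.220 as the adjusted p with an estimated correlation, and 0.191 after quantile normalization. Of 21 genes of the integrated stress response 10 fell and 5 rose. The serine synthesis gene Psat1 and Mthfd2, of mitochondrial folate metabolism, fell to 0.507 and 0.410 of control, and Ddit4, an inhibitor of mTORC1, rose 2.21-fold, with an adjusted p of 0.0193 and an adjusted p of 0.492 with an estimated correlation.

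Markers of other cell types and signalling genes gave further calls near the threshold. Of 14 oligodendrocyte lineage genes 9 rose and 2 fell, with the transcription factor Myrf up 5.18-fold, the myelin enzyme gene Cnp up 1.92-fold and the transcription factor Nkx2-2 down to 0.548 of control, at an adjusted p of 0.0248 and an adjusted p of 0.489 with an estimated correlation. Of 5 endothelial genes 4 rose. Egfl7, a secreted vascular protein, went from 4.63 ± 1.01 to 34.6 ± 5.33 TPM and the VEGF receptor gene Kdr from 0.532 ± 0.185 to 3.59 ± 0.323 TPM, with an adjusted p of 0.0376 and an adjusted p of 0.191 with an estimated correlation. Of 15 oxidative stress genes 9 rose and 1 fell, with the glutathione transferase gene Gsta4 up 6.61-fold, ferritin heavy chain Fth1 up 1.96-fold and metallothionein Mt1 down to 0.746 of control. That list had an adjusted p of 0.0481, an adjusted p of 0.395 with an estimated correlation, and 0.0509 after median-of-ratios scaling. Of 19 Wnt pathway genes 10 rose and 1 fell, among them Sfrp1, a secreted Wnt antagonist, up 3.02-fold, the receptor Fzd5 up 2.07-fold and the receptor Fzd1 down to 0.783 of control. The Wnt list had an adjusted p of 0.0494, an adjusted p of 0.195 with an estimated correlation, 0.0509 after median-of-ratios scaling and 0.0673 with a replicate block. Hdac1 rose 1.67-fold (log2 fold change 0.74, adjusted p 7.8e-09) and Hdac3 1.09-fold (0.12, adjusted p 0.0402). The call of Hdac3 ended after median-of-ratios scaling, where its change was 0.02, and also without a filter, without trend and in the fit of 8 libraries (adjusted p 0.00492 to 0.745 over the alternatives). Hdac2, Hdac8, Ep300 and Crebbp did not pass, at -0.04, 0.01, -0.16 and -0.12, and the signs of Hdac2 and Hdac8 turned with scaling. Radial glia genes had 12 higher and 6 lower of 25 and no call (adjusted p 0.524). Adjusted over the list alone, the counts for called lists were unchanged except for the integrated stress response (5 higher and 11 lower).

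In this comparison 9668 of 14857 genes passed in limma, 5561 higher and 4107 lower, with 1616 and 376 changed at least 2-fold. With median-of-ratios scaling 4699 were higher and 5087 lower. Camera called 17 of 40 lists, 10 upward and 7 downward, and 1 (interferon) with an estimated correlation. All 4 MS-275 libraries lay beyond all 4 controls for 60 of the 62 named genes that passed, and 3 of 4 did for Cox6a1 and Hdac3, a count that the naming rule largely fixes.

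The difference between MS-275 and crotonate was tested directly, which asks where the responses to the fatty acid and the inhibitor part. Il25, a cytokine, lay at 0.651 ± 0.183 TPM with crotonate and 10.1 ± 0.564 TPM with MS-275 (SD, n = 4 each), a log2 difference of 2.76 (SE 0.11). Casq1, a calcium store protein of muscle, Bmf, a pro-apoptotic BCL2 family member, Lrrc32, which anchors TGF-beta, and Camk2a, a calmodulin-dependent kinase, were 8.72-fold, 5.42-fold, 4.44-fold and 4.52-fold higher with MS-275. Scg2 lay at 24.7 ± 4.28 TPM with crotonate and 4.42 ± 1.00 TPM with MS-275, a log2 difference of -2.25 (SE 0.19). Cplx2 was lower with MS-275, at 0.252 of the crotonate level, as were Anks1b, Neil3 and Begain, at 0.325, 0.307 and 0.257. The doses were 10 mM for crotonate and 1 µM for MS-275, at the same 24 h, so the values compare these doses and not the compounds at matched potency.

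Both cell cycle lists were lower with MS-275 in every tested member. The 30 G2/M genes differed by a median of -0.90, with Bub1 and Cdc20 at 0.468 and 0.369 of the crotonate level, an adjusted p of 5.4e-19 and an adjusted p of 0.208 with an estimated correlation. The 28 G1/S genes differed by -0.75, with Mcm7 and Mcm4 at 0.559 and 0.530, an adjusted p of 8.5e-16 and an adjusted p of 0.0995 with an estimated correlation. Of 22 fatty acid oxidation genes 12 were higher, with the acyl-CoA dehydrogenase gene Acadl and Etfdh, of electron transfer, higher by 0.47 and 0.38 on the log2 scale, at an adjusted p of 3.3e-04 and an adjusted p of 0.208 with an estimated correlation. Of 21 oxidative phosphorylation genes 15 were lower, with Ndufs1 of complex I at 0.773 and Atp5a1 at 0.821, an adjusted p of 4.5e-04 and an adjusted p of 0.293 with an estimated correlation. Of 17 interferon genes 9 were higher and 1 lower. Rsad2 and the ubiquitin-like modifier Isg15 were 4.04-fold and 6.08-fold higher and B2m was at 0.824, with an adjusted p of 5.8e-04 and an adjusted p of 0.0825 with an estimated correlation. Of 11 writers 6 were lower, with Naa10 at 0.611 and Hat1 at 0.653, an adjusted p of 0.0119 and an adjusted p of 0.208 with an estimated correlation. These 6 did not include Ep300 and Crebbp.

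The remaining 3 calls had an adjusted p of 0.0426. Of 23 cholesterol genes 14 were lower and 2 higher, with Ebp, a sterol isomerase, at -0.83 on the log2 scale and Hmgcs1, of the mevalonate pathway, 1.36-fold higher. Of 19 astrocyte genes 10 were higher and 3 lower, with the calcium-binding protein S100b and the chaperone clusterin (Clu) 2.22-fold and 2.05-fold higher and the connexin Gja1 at 0.686. Of 5 endothelial genes 3 were higher, with Egfl7 3.27-fold higher and Ly6c1 at 0.719 ± 0.538 TPM with crotonate and 4.76 ± 1.45 TPM with MS-275. The adjusted p with an estimated correlation were 0.685, 0.652 and 0.208. After median-of-ratios scaling they were 0.0516, 0.0519 and 0.0519, after quantile normalization 0.0997, 0.0740 and 0.0740, and with a replicate block endothelium had 0.0522. Hdac1 and Hdac3 were higher with MS-275 by 0.40 and 0.18 on the log2 scale and Hdac2 differed by -0.18, all with adjusted p of 0.00704 or less. Hdac8, Ep300 and Crebbp did not pass, at -0.27, -0.27 and -0.19. Adjusted over the list alone, the counts for called lists were unchanged except for writers (1 higher and 9 lower), cholesterol (2 higher and 15 lower) and interferon (10 higher and 1 lower). Of 14857 genes 6933 passed in limma, 2868 higher and 4065 lower with MS-275, and 380 at least 2-fold. Camera called 9 of 40 lists, 4 upward and 5 downward, and 0 with an estimated correlation.

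The overlap of both responses shows how far crotonate and MS-275 moved the same genes. H2-Ab1, Tpm2, Mgarp, Ucp2, Vgf, Celf4 and Rian rose with both, and Kif11, Mcm7, Brd2 and Brd3 fell with both. Of the genes tested, 3813 rose with both treatments, beside 1795 for independent lists of these sizes, and 1932 fell with both, beside 651. Because both contrasts use the same 4 controls, chance alone links them. With 2 controls for each contrast, so that none is shared, 3088 rose and 1444 fell with both (mean of 6 splits). Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.802, 0.502 on average in 100 simulations of unchanged groups against the same controls and 0.710 with separate controls. The covariance was 0.268, beside 0.0148 in the simulations and 0.251 with separate controls. Genes were simulated independently of each other, so the simulations hold no correlation between genes.

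In forebrain explants, where the question is whether crotonate changes the tissue, the values are the authors' own fold changes, their SE and their adjusted p, from 3 control and 3 crotonate libraries. Hspa1b and Hspa1a, inducible chaperones of the HSP70 family (chromosome 17, 34956429 to 34959238 and 34969359 to 34972156), were higher by 1.94 (SE 0.05) and 1.89 (SE 0.05) on the log2 scale. Kpna2, a nuclear import receptor, was higher by 1.86 (SE 0.13) and Rpl30, a ribosomal protein, by 1.51 (SE 0.07). The processed pseudogenes Rps3a2 and Rps3a3 were listed at 1.87 and 1.68, and their near-identical copies elsewhere make these values uncertain, as for Tpm3-rs7, at -1.82. Otx2, a transcription factor of the forebrain and choroid plexus (chromosome 14, 48656781 to 48667644), had -1.41 (SE 0.15), Bhlhe40, a transcriptional repressor, -1.11 (SE 0.12), and Lypd10 -1.73 (SE 0.18). Matn2 and Lama3, both of the extracellular matrix, Syt17, Greb1 and the histone pseudogene Hist1h2al were lower, between -1.12 and -1.56. The Y-linked genes Eif2s3y, Kdm5d, Ddx3y and Uty had log2 fold changes of 13.02, 12.45, 12.20 and 10.02, and Xist, the RNA of the inactive X chromosome, -1.68 (SE 0.10). The mean normalized counts of these Y-linked genes over all libraries were 910.1, 634.4, 552 and 254.6. With such means, the fold changes put the Y-linked genes close to 0 in the controls as a group. The table used holds no values per library, so single controls cannot be read, and these numbers are no measure of a fold. The X-linked genes Kdm6a, Ddx3x, Eif2s3x and Kdm5c, which escape X inactivation, had -0.38, -0.16, -0.35 and -0.39. The groups therefore differ in the sex of their embryos, so differences between embryos cannot be told apart from crotonate in the explant values.

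Lists of explant genes were compared with 10000 random lists of like size and expression. Of 25 ribosomal protein genes 17 rose and none fell (median 0.10), with Rpl13 and Rplp1 at 0.21 and 0.24, and of 11 heat shock genes 8 rose (median 0.15). Of 17 genes of the ventral forebrain and GABAergic neurons 13 fell and 1 rose, with a median of -0.38. Nkx2-1, a transcription factor of the ventral forebrain, had -0.99, the GABA-synthesizing enzyme gene Gad2 -0.38 and Foxp1 0.15. Of 10 Cajal-Retzius genes 7 fell (median -0.43), including the secreted glycoprotein reelin (Reln), at -0.24, and Lhx5, at -0.92. Of 9 erythroid genes 6 fell (median -0.46), with the globins Hbb-bs and Hbb-y at -0.44 and -0.43. Of 25 radial glia genes 12 fell and 4 rose (median -0.12), with Sox2 at -0.33, Notch1 at -0.26 and Fabp7 at 0.11. Notch pathway genes had 6 lower and 1 higher of 20, with the Notch target Hes5 at -0.62 and Rbpj, the transcription factor of the pathway, at 0.33, and Shh pathway genes 4 lower and 2 higher of 12, with Gas1 at -0.33, Ptch1 at -0.21 and Cdon at 0.25. Basal progenitor genes had 6 higher and 3 lower of 17, with a median of -0.08 and a mean of 0.07, which differ in sign. Their members Nhlh1 and Sstr2 had 0.52 and 0.47.

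Cell cycle, metabolic and other lists of the explants fell as well. Of 30 G2/M genes 23 fell (median -0.19), with Top2a at -0.24 and Mki67 at -0.18, and of 28 G1/S genes 15 fell (median -0.18), with Ccnd1 at -0.46 and Uhrf1 at -0.36. Of 19 glycolysis genes 12 fell (median -0.24), with Pfkfb3 at -0.55 and Gpi1 at -0.34, and of 11 mitochondrial transcripts 7 fell and 1 rose, with mt-Nd5 at -0.69, mt-Nd1 at -0.32 and mt-Atp8 at 0.10. Of 23 cholesterol genes 9 fell and 3 rose, with Hmgcs1 at -0.24 and Sc5d at 0.15. Of 22 imprinted genes 14 fell and none rose, with Mest at -0.44 and Grb10 at -0.32. Immediate early genes had 5 lower and 3 higher of 18 (Fosb -0.71, Jund -0.42, Jun 0.25), astrocyte genes 5 lower and 1 higher of 15 (Fgfr3 -0.47, Id4 -0.20, Aldoc 0.30), oxidative stress genes 5 lower and 1 higher of 13 (Prdx1 -0.11, Ftl1 -0.06, Fth1 0.08) and matrix and mesenchyme genes 3 lower of 17 (Col3a1 -0.76, Fn1 -0.16). Dorsal telencephalon genes, with 4 higher and 4 lower of 14, lay inside the random range, and 0 of 7 interferon genes were called. Ep300 had -0.14, Crebbp -0.10 and Hdac2 0.05, all called, and Hdac1, Hdac3 and Hdac8 did not pass, at -0.03, 0.00 and 0.06.

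**Figure D3:**
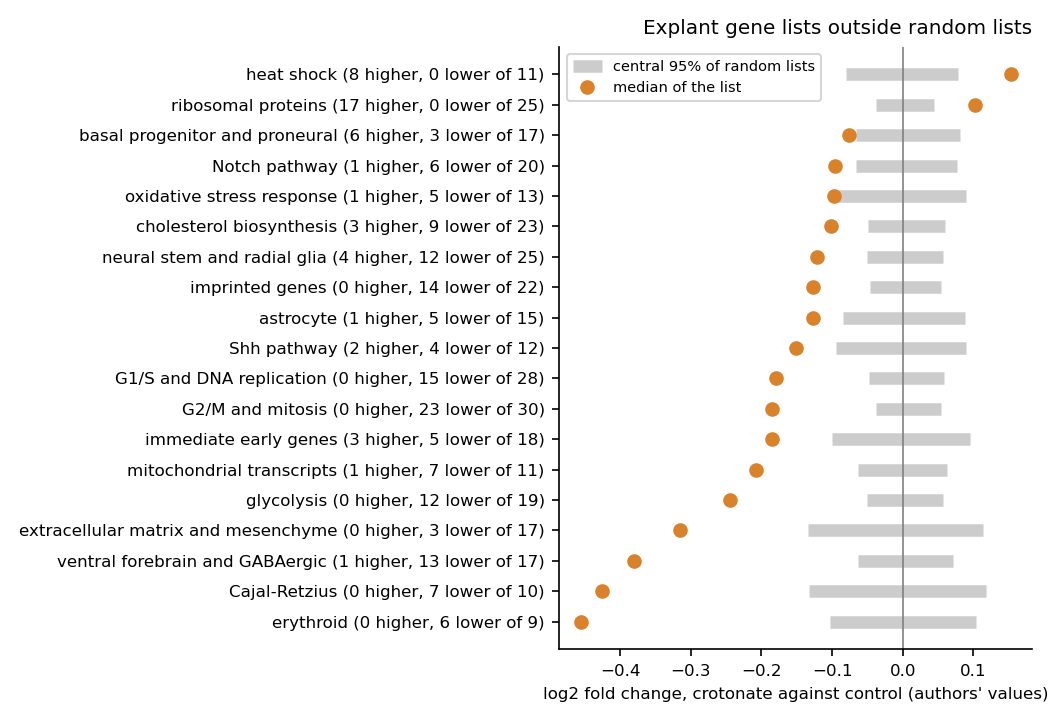
Median log2 fold change of explant gene lists, crotonate against control (orange points, the authors' values), beside the central 95% of 10000 random lists of like size and expression (grey bars). The 19 lists outside the bars run from the erythroid list at -0.46 to the heat shock list at 0.15.

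By the authors' adjusted p, 2936 of 14507 tested genes differed between crotonate and control explants, 1521 higher and 1415 lower, with a median size of 0.20 on the log2 scale. At least 2-fold changes were found for 83 genes, 35 higher and 48 lower, of which 16.9% were pseudogenes beside 2.51% of tested genes. Of the genes called, 2840 were autosomal, 91 lay on X and 5 on Y. Adjusted over the list alone, the counts of lists outside the range were radial glia 5 higher and 13 lower, basal progenitor 6 and 6, ventral forebrain 1 and 14, astrocyte 1 and 6, G1/S 1 and 18, G2/M 0 and 25, cholesterol 3 and 11, glycolysis 1 and 16, ribosomal 19 and 0, heat shock 9 and 2, immediate early 3 and 6, Notch 1 and 8, Shh 2 and 5 and imprinted 0 and 15, and those of the others were unchanged. Of 41 lists 19 lay outside the central 95% of random lists, 2 above and 17 below, where 2.05 are expected by chance for unrelated genes, and no correlation between genes could be estimated. The labels do not say that the explant replicates are biological, so the p may measure only the spread between these samples, which may be technical. For 4650 genes with a mean of at least 1000 normalized counts the median SE was 0.0367. That is 1.45 times the SE from counting alone with 3 libraries per group, so the p may not measure variation between embryos. The groups also differ in the sex of their embryos, so these counts are not of crotonate alone.

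The explant response was compared with that of NSPCs to see whether the same genes respond in tissue. The chaperone gene Hspa2, Ston1, the interferon-induced gene Ifit2 and the immediate early gene Egr1 were higher in both, at 0.90, 1.56, 0.86 and 0.77 in NSPCs and 1.12, 0.87, 0.75 and 0.66 in explants, and Cdca3, a cell cycle gene, and Zfp36l2, an RNA-binding protein, were lower in both, at -0.66 and -0.60 in NSPCs and -0.59 and -0.53 in explants. These 6 genes were chosen after their values were seen. Among 12926 genes tested in both, 473 were higher in both, beside 462 expected (odds ratio 1.04, two-sided Fisher's exact p 0.491), and 414 were lower in both, beside 228 (odds ratio 2.46, p 2.2e-40). Genes are not independent, so these p describe the tables. Of 1460 genes called in both 887 moved the same way (60.8%), and across all genes tested in both Pearson's r was -0.00390 and Spearman's rho 0.0637. Interferon, synapse and REST-repressed lists were called upward in NSPCs at the preset correlation and lay inside the random range in explants. Imprinted genes rose in NSPCs and fell in explants. With an estimated correlation the synapse, imprinted and REST-repressed calls ended (adjusted p 0.0539, 0.0539 and 0.332), and with a replicate block as well that of interferon (0.187). The difference between the NSPC and explant responses was not tested, since strain, preparation and RNA selection differ with it. The labels give no dose or time of crotonate for the explants, so the exposure cannot be taken to match that of NSPCs.

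ChIP peaks were compared to ask how crotonate and MS-275 change where Kcr and Kac are found in NSPCs, with 1 library per list and no test between treatments. The widest Kcr peaks found with crotonate and not in control lay at Lncpint (chromosome 6, 31216647 to 31218437), at Dach1, a transcription factor gene (chromosome 14, 98167592 to 98168881), and at Adm, the adrenomedullin gene, and Gm28863 (chromosome 7, 110627893 to 110629078). Adm rose with crotonate by 0.22 on the log2 scale (adjusted p 0.0394), Dach1 did not pass at 0.20 (adjusted p 0.157), nor did Gm28863 at 0.18 (adjusted p 0.713), and Lncpint, at 0.243 TPM in control, was below the level tested. The widest Kac peaks gained with crotonate lay at Hs3st3a1 (chromosome 11, 64435282 to 64436565), at the protocadherin gene Pcdh7 (chromosome 5, 57716438 to 57717553), which rose by 0.35, and at Lor (chromosome 3, 92080696 to 92081806), which did not pass at 0.17. With MS-275 the widest gained Kcr peaks lay at Syt17 (chromosome 7, 118447496 to 118448488) and Sez6l (chromosome 5, 112549581 to 112550400), which rose by 1.20 and 1.12, and at Septin4 (chromosome 11, 87578590 to 87579352), which the expression table does not name. The widest gained Kac peaks with MS-275 lay at Fblim1 (chromosome 4, 141599042 to 141599953), up by 2.03, at chromosome 13, 107675863 to 107676707, with no annotated gene, and at Bdnf, a neurotrophin gene (chromosome 2, 109677245 to 109677984), up by 0.64.

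Kcr peaks numbered 17669 in control, 23301 with crotonate and 5845 with MS-275, covering 5.91, 7.63 and 1.84 Mb. Of the crotonate peaks 51.9% overlapped a control peak and 11204 did not, while 67.4% of control peaks were found again and 5767 were not. Of the MS-275 peaks 50.9% overlapped a control peak, and 17.1% of control peaks were found again. Kac peaks numbered 23427, 21616 and 7555, covering 8.24, 7.78 and 2.26 Mb. With crotonate 66.0% of Kac peaks overlapped a control peak, with 7357 gained and 9146 lost, and with MS-275 63.1% did, with 2788 gained and 18741 lost. Within 1 kb of an annotated gene end lay 63.7% of Kcr peaks in control, 61.6% with crotonate and 48.0% with MS-275, and 59.2%, 58.8% and 43.2% of Kac peaks. Of Kcr peaks 80.7% overlapped a Kac peak in control, 62.0% with crotonate and 31.1% with MS-275. Of Kac peaks 59.5%, 64.6% and 24.4% overlapped a Kcr peak. With crotonate the share of Kcr peaks was thus lower and that of Kac peaks higher, and each share depends on the lengths of both lists. Peak numbers depend on depth and enrichment, which the files do not give, and the deposited NSPC lists hold no scores.

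**Figure D4:**
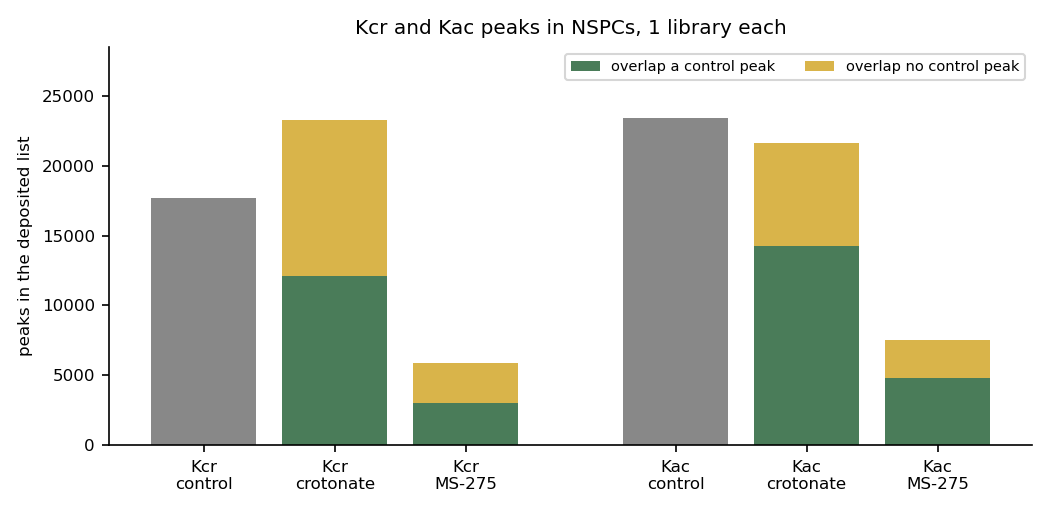
Number of Kcr and Kac peaks in the deposited NSPC lists (1 library each), split for crotonate and MS-275 into peaks that overlap a control peak by at least 1 bp (green) and peaks that do not (yellow). Both antibodies gave the fewest peaks with MS-275, 5845 and 7555.

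Peaks gained at genes were set beside the RNA of the same treatment. Of 19 tested REST-repressed genes 8 had a Kcr peak within 1 kb of a gene end with crotonate and none in control, as did 8 of 17 interferon genes, 7 of 29 synapse genes and 4 of 5 Cajal-Retzius genes, while 8 of 30 G2/M genes lost one and 1 gained one. Lists that were not called upward gained peaks too, with 8 of 19 Wnt, 7 of 19 glycolysis and 5 of 21 integrated stress response genes, and over all tested genes with a position 2149 of 13773 gained one. The G1/S genes, called downward at the preset correlation, gained 4 and lost 2. Of 20 imprinted genes, a list called upward at that correlation, 2 gained one. With MS-275 the interferon genes gained 1 and lost 2 and the REST-repressed genes gained 2, although both lists were called upward at the preset correlation. With an estimated correlation the calls of the G1/S, imprinted and REST-repressed lists ended, and with a replicate block as well that of interferon. These lists were chosen after their values were seen, and their differences from other genes were not tested. The 2149 genes that gained a Kcr peak with crotonate had a median log2 fold change of 0.34 (95% bootstrap interval 0.31 to 0.37), and 52.3% of them rose and 8.47% fell. The 7010 genes with a peak in both had a median of 0.02, and the 843 that lost one -0.02. The difference between gained and kept was 0.32, beside a mean of 0.16 when classes were permuted within bins of control expression (permutation p 1e-05, the smallest that 100000 permutations can give), and that between lost and kept was -0.04 (p 3.2e-04). With MS-275 the 400 genes that gained a Kcr peak had a median of 0.71 and the 1917 that kept one 0.02, a difference of 0.68 beside a permuted mean of 0.28 (p 1e-05, the same limit). The 5936 genes that lost one had a median of -0.05, a difference of -0.07 (p 1.3e-04). Genes with a gained Kac peak had medians of 0.49 with crotonate (1163 genes) and 0.72 with MS-275 (254 genes), differences of 0.46 and 0.69 to genes that kept one, beside permuted means of 0.20 and 0.33 (p 1e-05 each). Genes that lost a Kac peak differed by -0.03 (p 0.006) and -0.07 (p 4e-05). Genes with no Kac peak in either list were also higher relative to kept ones, by 0.19 with crotonate (p 0.0018) and 0.29 with MS-275 (p 0.0092), beside permuted means of 0.17 and 0.25. Genes with no Kcr peak in either list differed from kept ones by 0.17 with crotonate (p 1.2e-04) and 0.24 with MS-275 (p 0.025). The permuted means were 0.15 and 0.21, so most of each difference follows control expression. Among genes above 5 TPM the differences of genes with no Kcr peak were 0.04 (p 0.092) and 0.06 (p 0.16). The differences of genes with a gained Kcr peak were smaller above 5 TPM as well, at 0.13 with crotonate and 0.36 with MS-275 (p 5e-04 each, the smallest that 2000 permutations can give). Genes are not replicates, and genes that gained a Kcr peak with crotonate had a lower median control level (log2 of TPM plus 1, 3.21) than genes that kept one (4.93).

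**Figure D5:**
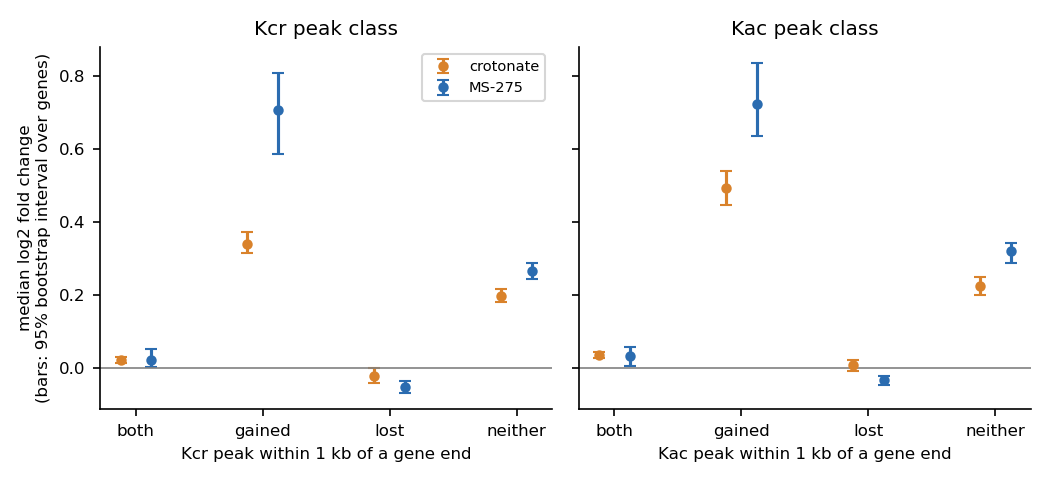
Median log2 fold change of genes by whether a Kcr (left) or Kac (right) peak within 1 kb of a gene end was found in control and treated lists (both), gained, lost or in neither, for crotonate (orange) and MS-275 (blue), with 95% bootstrap intervals over genes. Genes that gained a Kcr peak had medians of 0.34 and 0.71.

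In the untreated forebrain the lists of H3K9cr and H3K9ac peaks were compared to ask how far both marks share places. H3K9cr had 12492 peaks over 12.1 Mb and H3K9ac 16610 over 21.1 Mb, with median fold enrichments of 8.38 and 12.7. Of H3K9cr peaks 99.6% overlapped an H3K9ac peak, while 68.5% of H3K9ac peaks overlapped an H3K9cr peak. With equal numbers of top peaks these shares were 97.2% and 88.7%, so the gap between them depends on the number of peaks taken. Within 1 kb of a gene end lay 82.3% of H3K9cr and 73.2% of H3K9ac peaks. The 11011 genes with both marks had a median of 28.1 TPM in the forebrain RNA library, and 90.2% of them reached 1 TPM. The 2148 genes with H3K9ac alone had a median of 2.21 TPM, the 12 with H3K9cr alone 0.682 TPM and the 25014 with neither 0 TPM. A gene whose H3K9cr peak was missed through weaker enrichment would also be counted as H3K9ac alone, which was not tested. There were no replicates of these libraries, so no error is given.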

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

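The test of tissue regions in the explants and that of the scale of the TPM values were chosen only after the result was seen, and so was the count of splits for single lists.

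For each gene named in the text the 4 NSPC libraries of a group were compared with each other. In 39 of 609 groups of 4 the highest or lowest library lay so far from the others that its gap, as a share of the range, exceeded Dixon's 95% critical value, and chance gives about 1 in 20, or 30.5. Of these 39, 8 were in crotonate replicate 2, where (in TPM, with the range of the other 3 libraries) Bmf was 4.451 (1.919 to 2.334), Fblim1 19.74 (13.65 to 14.28), Gpc3 18.12 (15.62 to 15.98) and Mdfi 15.6 (10.08 to 10.91), and, on the low side, Cdc20 98.24 (116 to 118.4), Cdca2 23.86 (29.47 to 30.3), Fdps 261.2 (308.2 to 317.4) and Hat1 99.27 (110.2 to 110.6). In crotonate replicate 1 Crebbp was high at 12.8 TPM, Fosb at 4.509, Hist1h2al at 20.89, Hspa1b at 10.25, Rps3a3 at 0.1777 and mt-Nd1 at 11850. Replicate 3 was high for Spc24 at 54.33 TPM, and replicate 4 for Mt1 at 788 and low for Sv2a at 30.49. With MS-275, replicate 1 was high for Brd2 (120 TPM) and Egfl7 (42.64) and low for Mthfd2 (17.45), and replicate 2 was high for Hist1h2af (0.7517) and Rps3a2 (0.4387) and low for Fdps (213.9) and Sqle (148.3). Replicate 3 with MS-275 was high for Ebp (19.69 TPM) and Gpc3 (12.34) and low for Rsad2 (8.675) and Sox2 (247), and replicate 4 was high for Gm28863 (1.161) and low for Celf4 (14.31). Among the controls, replicate 1 was low for Kif11 (107.4 TPM) and Mest (544.3), and replicate 2 high for Snurf (4.833) and mt-Nd1 (12900). Control replicate 3 was high for Matn2 (3.963 TPM) and Uhrf1 (167.1) and low for Nhlh1 (0.0346) and Rps3a2 (0.0), and replicate 4 high for Notch1 (69.24).

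Xist and the Y-linked genes stand among the 2936 genes that the authors called in the explants. Embryos of different sex in the 2 groups account for these: Y-linked genes were nearly absent in the controls as a group, and Xist had -1.68. The median log2 fold change of Kdm6a, Ddx3x, Eif2s3x and Kdm5c, which escape X inactivation, was -0.3664. The embryos used thus differ together with the treatment, and for the other called genes these cannot be told apart. An effect confined to the sex chromosomes is argued against as the source of all calls, as a share of 0.0327 of the called genes lies on the X or Y chromosome. The share over all tested genes was not set beside it. Other differences between the embryos could lie in autosomal genes, so this share does not bear on them. A different make-up of regions in the tissue stays open, with a median of the ventral list minus that of the dorsal list of -0.3685, and the response shared with NSPCs was left undecided by a share of 0.6075 moving the same way with a correlation of -0.0039. A response to crotonate in the remaining genes stays open, since the share met the bound set for that test and the correlation did not.

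Fewer peaks were called with MS-275 by both antibodies. Weaker enrichment or lower depth in those libraries may account for this: of the control Kcr peaks 9.111% were found again among the narrowest 10% and 41.73% among the widest 10%, a ratio of 4.58, and for Kac 9.432% and 50.3%, a ratio of 5.333. Wide control peaks were found again more often with crotonate too, from 45.05% to 92.81% for Kcr and from 35.21% to 94.19% for Kac. The ratios therefore do not tell weaker enrichment from a real loss. A loss where expression fell was left undecided, with the median log2 fold change of genes that lost a Kcr peak -0.0725 relative to genes that kept it. Each treatment has 1 library per antibody, so a real loss of marks stays open.

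More genes rose than fell with crotonate on the scale of the TPM values. That scale may account for the excess in the counts: after median-of-ratios scaling the share of higher genes among those changed was 0.454. Counts turned to 3503 higher and 4213 lower with that scaling, and to 3091 and 3685 after quantile normalization. Both centre the change of the typical gene, whose median log2 fold change went from 0.0884 to -0.0281 and -0.0458. They lower the share of higher genes whether the excess is real or not, so this test cannot tell an effect of the scale from a real excess. Rises among weakly expressed genes were found, as the 4953 least expressed genes had a median log2 fold change of 0.3189, 0.3457 above the 4952 most expressed, and it stayed positive at 0.2368 after the scaling. A few genes taking a different share of the transcripts is argued against, since the 100 highest genes held 33.1% of TPM in control and 33.2% with crotonate, 0.11 percentage points apart. A wide rise of weakly expressed genes is a biological candidate that these values leave open.

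Other splits of the same libraries were run in the fits of 8 libraries. For the genes changed, 1 of 35 splits, the real one, gave as many in each comparison. It gave 6769 genes for crotonate (highest other 8), 9312 for MS-275 (8) and 6860 for the difference (9). The replicate numbers pair the libraries, so only the 8 splits that part all 4 pairs are comparable, and there the highest other was 0. Among 8 splits the real one can at best be 1 of 8, so the splits alone do not exclude chance. For the number of lists called chance could not be excluded, as 8, 6 and 15 of 35 splits gave as many as the real 12, 14 and 7, with 14, 18 and 12 as the highest others, and 11, 12 and 10 among the splits that part the pairs. For each list called, the real split moved it most of the 35 in 13 of 13 for crotonate, 17 of 17 for MS-275 and 7 of 9 for the difference. Over all 40 lists this held for 25, 25 and 21, so it also held for lists without a call. For the overlap of the treatments 1 of 100 splits of the 12 libraries was as large (5745 genes, highest other 5138). These splits ignore the pairing and still carry the treatment effects, so this rank does not exclude chance. For the correlation of the treatments 19 of 100 splits were as high (0.8019, highest other 0.9563), so these splits do not exclude chance there either. The splits mix treated with control libraries. In 100 simulations of unchanged groups against shared controls the highest correlation was 0.5585, below the real one. Genes and libraries were simulated independently, so these simulations leave out the correlation between genes and do not exclude chance either.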

How the results depend on the processing

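Quantile normalization of the lists, the replicate block with estimated correlation, the autosomal genes of the explants, gene bodies and median-of-ratios scaling for peak classes and for the overlap of NSPCs and explants were tests chosen only after the data were seen.

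Changed genes stayed within 1.5 times the reported counts under the alternatives run but 1: 5987 to 7716 for crotonate, 8132 to 10186 for MS-275 and 6228 to 7236 for their difference. Requiring an absolute log2 fold change of at least 1 left 931, 1992 and 380, which follows from the added condition, as do 83 genes in the explants and 0 shared by NSPCs and explants in the same direction. With single libraries left out the counts were 6458 to 6843, 9136 to 9378 and 6286 to 6411. The overlap of the treatments was 4532 to 6302 genes (5193 to 5565 with a library left out). Their correlation was 0.7762 without a filter, 0.8259 with a minimum of 5 TPM, 0.7609 after quantile normalization and 0.7104 with 2 controls for each treatment, where the controls are no longer shared. The cause of the others was not tested (0.7888 to 0.8109 with a library left out). The explant count was 2502 without the filter, 2938 with a higher one and 2840 for autosomal genes, and the overlap with NSPCs 700, 935 and 932 with no filter, block and scaling.

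The lists depend on whether the correlation between genes is preset or estimated. With it estimated per list, camera called 1 list for crotonate, 1 for MS-275 and 0 for the difference, and with the replicate block as well 0, 0 and 0. The cause was not tested, and endothelium lost its call with an estimate of -0.157, below the preset. Fry, which tests members against 0 and not against other genes, called 30, 35 and 22. The block alone gave 12, 17 and 8, median-of-ratios scaling 13, 16 and 6 (11, 15 and 6 of them as reported) and quantile normalization 16, 18 and 6 (11, 16 and 6), and no called list turned under these scalings. With a library left out there were 12 to 15, 15 to 18 and 6 to 10. The call for heat shock with crotonate ended without control 1 or crotonate 2, 3 or 4 (adjusted p 0.05455 to 0.08741), for Wnt with MS-275 without control 1 or MS-275 1 or 4 (0.0554 to 0.07123) and for oxidative stress without control 2 or MS-275 1 or 3 (0.05326 to 0.06782). For the difference, cholesterol synthesis was lost without crotonate 1 or 4 or MS-275 2 (0.06625 to 0.1292), astrocyte genes without crotonate 2 or 4 or MS-275 1 (0.0513 to 0.09888) and endothelium without crotonate 4 (0.05635; 0.03513 to 0.05635 over libraries left out). The block ended the heat shock, Wnt and endothelium (difference) calls and that of Cox6a1, and added extracellular matrix with MS-275 and 7 named genes. It changed no other call among 120 lists and 191 genes.

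Of 720 values of lists under other alternatives 569 kept direction and side of the threshold, 58 passed it, 92 fell short and 1 reversed: ribosomal proteins fell with crotonate under median-of-ratios scaling at an adjusted p of 0.02136 (0.005749 to 0.9378 over these alternatives). The lowest of these, 0.005749, belongs to an upward call, so the alternatives called that list in both directions. Of 1711 values of named genes 1668 kept both, 29 passed, 13 fell short (Rsc1a1 with a pseudocount of 0.1, no filter and no trend, Cox6a1 with no filter, no trend, scaling and block, Hdac3 with no filter, no trend, scaling and 8 libraries, Hdac2 with scaling and Mt1 with quantile normalization) and 1 reversed, Ctnnb1 with MS-275 at -0.0843 under that scaling (adjusted p 0.03119; 0.03119 to 0.7475). The cause was not tested for these 2. Leaving out libraries kept 925 of 952 values of lists and 1488 of 1525 of genes, where a list under 5 tested members has no value. Rsc1a1 lost its call in 7 of 8 (0.05162 to 0.09695), without each control but 4 and without each crotonate library, AA465934 without control 2 or crotonate 3, Hdac2 (crotonate) without crotonate 2 (0.05047; 0.00129 to 0.05047 over libraries left out), Cox6a1 without control 2 or 3 or MS-275 2 or 4, and Hdac3 (MS-275) without control 2 or 4 or MS-275 2, 3 or 4 (0.05993 to 0.126).

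An overlap of at least 50% lowers each share by construction: Kcr with crotonate 34.91%, with MS-275 29.12%, Kac 45.32% and 32.28%, Kcr in Kac 56.48%, 40.48% and 19.09% in control, crotonate and MS-275, and forebrain 67.2%. Merging within 1 kb gave Kcr 56.44% with crotonate, Kac 68.39% and 64.3%, and Kcr in Kac 84.05%, 67.19% and 32.81%, as wider peaks meet more often. The forebrain share of H3K9cr peaks was 99.91% at a -log10 q of at least 5 and 97.18% with equal numbers of top peaks. That of H3K9ac peaks was 69.26% and 88.66% (68.49% as reported), and the cause was not tested. The difference of genes with a peak in neither list lost its call above 5 TPM (0.0449 for crotonate, 0.059 for MS-275), and for MS-275 also with 3 kb (0.2395) and gene bodies (0.2407), with p up to 0.092 and 0.58 over the alternatives. The cause was not tested. Gained and lost Kcr classes kept direction and call, but above 5 TPM the difference of gained genes fell to 0.133 with crotonate (0.3159 as reported) and 0.3553 with MS-275 (0.6829). For Kac classes no alternative was run. Forebrain genes with both marks had a median log2 of 4.7164 with 3 kb, 4.942 at the stricter q and 5.2689 above 5 TPM (4.8622 as reported), the last since weak genes are left out.

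The stricter threshold and the top peaks were not run for NSPC lists, which hold no scores, and alternatives that need values per library (DESeq2, edgeR, pseudocounts, scalings, list tests, libraries left out) were not run for the explants. Library depth is not known, so what it limits could not be measured for weakly expressed genes or for peaks.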

Other observations

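All tests in this part were chosen only after the result was seen.

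Among genes changed by both treatments 235 moved in opposite directions, 121 of them higher with crotonate and lower with MS-275 and 114 the other way. As log2 fold changes with crotonate and with MS-275 these include Begain (0.77 and -0.75), Rgs16 (-0.75 and 0.75), Gbp3 (-0.61 and 0.69), Egr3 (0.51 and -0.59), Tnc (-0.45 and 0.46), Nkx2-2 (0.44 and -0.85), Cplx1 (0.37 and -0.41), Gria2 (0.44 and -0.37) and Sv2c (0.92 and -0.34), named here for their function after their values were seen.

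In the forebrain both marks lay at the ends of 28 of 28 genes of DNA replication, 30 of 30 of mitosis, 25 of 25 of ribosomal proteins and 11 of 11 acyltransferases. They lay at 0 of 39 Hox genes, 0 of 24 germline genes, 0 of 14 endothelial, 0 of 16 microglial and 0 of 11 erythroid genes, whose median was 344.8 TPM. The forebrain RNA held Xist at 144 TPM and Ddx3y at 21.8 TPM.

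Peaks on the X chromosome made up 3.018% of the forebrain H3K9cr list and 3.095% of the H3K9ac list. In NSPCs they made up 0.4924%, 0.3605% and 0.03422% of the Kcr lists of control, crotonate and MS-275, and 1.059%, 0.458% and 0.1059% of the Kac lists.

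Of the genes changed with MS-275 in NSPCs and called in the explants 58.61% moved the same way, with 572 higher in both (528.6 by chance) and 575 lower in both (396.7).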
